A study of Homo sapiens with 66 samples.

How the data were processed

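Skin biopsies of patients with diffuse cutaneous systemic sclerosis, a fibrosing autoimmune disease of the skin and internal organs, were profiled on expression microarrays. Per the labels, 1 forearm of each patient received C82, which the series title calls a beta-catenin inhibitor, and the other received placebo, for 28 days, and biopsies were taken at baseline and at day 28. The 66 arrays came from 17 patients. The 4 groups of 17 placebo baseline, 17 placebo day 28, 16 C82 baseline and 16 C82 day 28 biopsies were formed from the labels' treatment and time point, and 15 patients had all 4 biopsies. The other 2 patients had 3, and the missing biopsies were not analysed here. Per the labels' protocols, biopsies were kept in RNAlater, RNA was purified on columns, and biotin-labelled cRNA was made from total RNA for Affymetrix arrays.

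The deposited table holds log2 values of 22277 probe sets. The submitters' processing notes name affy and MAS5, with no version, as the tools, and a base-2 antilog of each array gave a mean of 500 after trimming 2% at each end, which is how the log base, the scale and the absence of centring were settled. MAS5 scales each array by itself and subtracts mismatch probes from perfect-match probes, so dim probe sets are noisy on the log scale. Values ranged from -4.83 to 14.92 and array medians from 6.97 to 7.36. Direction is not in doubt for a single-channel array. Scanner files and the date or batch of scanning were not used here, and no batch is given in the sources used here, so no test within batches was made. The number of patients, and not a read depth, limits the precision.

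Probe sets were named through the platform annotation, with symbols checked by Entrez gene number against RefSeq's gene table of GRCh38.p14, from which names only were taken. One symbol was listed for 19064 probe sets, several for 1043 and none for 2108, and 62 were Affymetrix controls. Probe sets with several symbols were not named. Of those with 1 symbol, 19052 matched by gene number and no symbol changed. The 52 probe sets for XIST or Y-linked genes were left out of all steps. For each of the 11939 remaining genes the probe set with the highest mean over all arrays was used. Genes under the 40th percentile of these means, a log2 value of 7.09, were left out, which left 7163.

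The values were tested as deposited, because the table was already on the log2 scale, in a linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with the 4 groups and the patient as a fixed block. All 66 arrays entered 1 fit with 46 residual degrees of freedom. From it 6 contrasts were read, namely the change from baseline to day 28 in each arm, the difference between these changes, the C82 minus placebo difference at day 28 and at baseline, and the mean change of both arms. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The labels give the same number to samples of the same patient, and deviations from the group means correlated with a median of 0.602 over 96 pairs of arrays of the same patient, against -0.052 over 2049 pairs of different patients.

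Gene lists were fixed before the data were examined. They held Wnt target and pathway genes, matrix, TGF-beta, interferon and lipid genes, stress and cell cycle genes and markers of the cell types and glands of skin. Of 33 lists, 31 had at least 3 tested genes. Those for skeletal muscle and red blood cells had 2 and 1 and were not tested. For each patient the mean log2 difference over a list was taken, and the mean over patients was tested with an exact two-sided sign-flip permutation test, adjusted over the 31 lists within a comparison. The test of list means has the patient as its unit. Camera tests with a preset correlation of 0.01 and with an estimated correlation were alternatives. Intervals are 95% confidence intervals.

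Genes were named by a rule set in advance. Among called genes with the fitted direction in at least 70% of patients, the 12 with the largest positive and the 12 with the largest negative difference were named. Where fewer than 10 genes passed, all that passed and the 5 with the smallest unadjusted p in each direction were named as not passing. The 3 members with the largest difference were named for a described list, and 13 further genes of Wnt signalling, fat, fibrosis, interferon and macrophages for the difference in change. AXIN2 and APCDD1 among these had no probe set with 1 symbol and were not analysed here.

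The procedure was tested on simulated tables with the real gene means, patient effects and residual spread of 7163 genes, in which 200 genes were changed by known amounts. For the difference in change between the arms, 25.5% of genes changed 1.19-fold, 75.5% of those changed 1.41-fold and 98.2% of those changed 2-fold were recovered. For the change in the C82 arm these shares were 48.5%, 89.3% and 99.4%, for the placebo arm 54.8%, 88.1% and 98.5%, and for both arms together 78.8%, 94.6% and 100%. Noise was drawn from a normal distribution independently for each gene and array. Correlation between genes and a patient's own response over time were left out. The shares hold for 200 changed genes and may overstate what could be recovered in the real table. Alternatives changed the filter, the normalization, the choice of probe sets, the floor of the values, the threshold, the block, the arrays' weights, a covariate for RNA degradation and the patients left out. A further 2 alternatives were added after the data had been seen, one without the array least like the others and one with keratinocyte and adipocyte list means as covariates.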

Results

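The 66 arrays measured transcripts in forearm skin of 17 patients with diffuse cutaneous systemic sclerosis, each of whom received C82 on 1 forearm and placebo on the other for 28 days. C82 is described in the series title as an inhibitor of beta-catenin, the transcriptional coactivator of canonical Wnt signalling. Mean array medians were 7.20 ± 0.05 (SD, n = 17) and 7.23 ± 0.09 (n = 17) in the placebo arm at baseline and day 28, and 7.22 ± 0.08 (n = 16) and 7.25 ± 0.07 (n = 16) in the C82 arm, on the log2 scale. The log2 ratio of 3' to 5' probe sets of GAPDH and actin, a measure of RNA degradation, averaged 0.04 to 0.07 in the 4 groups, and its mean changes and differences were between -0.003 and 0.03 with exact sign-flip permutation p-values from 0.339 to 0.945 over the 6 comparisons. The array median was higher at day 28 by 0.03 ± 0.05 (SD, n = 15) in the C82 arm (exact sign-flip permutation p = 0.033, not adjusted), by 0.03 ± 0.09 (n = 17) in the placebo arm (p = 0.110) and by 0.03 ± 0.06 (n = 15) over both (p = 0.049).

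For most tissue compartments the patient accounted for the larger part of the spread left after the 4 groups. The patient accounted for 87.1% of the variance of the B and plasma cell list, 86.8% of the T and NK cell list, 84.9% of the interferon-stimulated genes and 82.8% of the collagens and matrix list, after the 4 groups. The share was 69.3% for the adipocyte list, 51.5% for the hair follicle list and 29.6% for the basal keratinocyte list. These are raw drops in the residual sum of squares when the patients are added. Part of each share would thus arise without any difference between patients, which matters most for the smallest. One placebo day 28 array stood apart from all others, with a median Spearman correlation of 0.795 to the rest against 0.890 for the next lowest. In it the adipocyte list lay 2.87 log2 units above the mean of the same patient's other biopsies. The basal and differentiated keratinocyte lists lay at -3.99 and -4.95, and the hair follicle list at -4.51. Without this array the patient's share for the basal keratinocyte list was 73.2%.

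The main question of the design was whether skin changed differently under C82 than under placebo. No gene of 7163 met an adjusted p under 0.05 for the difference between the changes of the 2 arms in limma, where 247 had an unadjusted p under 0.05 and chance alone gives 358. The smallest adjusted p was 0.994. Of the genes with the smallest p-values, none of which passed, ACAT2, an enzyme of sterol synthesis, had a log2 difference in change of 0.66 ± 0.18 (SE, 15 patients with all biopsies, higher in 12), and SOAT1, which esterifies cholesterol, of 1.01 ± 0.30 (higher in 10 of 15). EIF4E, the cap-binding translation factor, was at 0.27 ± 0.08, ATP6V0B, a subunit of the vacuolar proton pump, at 0.21 ± 0.06 and MSRB1, a methionine sulfoxide reductase, at 0.48 ± 0.14. The smallest p-values in the other direction belonged to USP21 (-0.37 ± 0.11), RABL3 (-0.32 ± 0.10), PCBP4 (-0.42 ± 0.14), VPS11 (-0.25 ± 0.08) and H6PD (-0.20 ± 0.07). For 97.3% of the genes the 95% interval lay within 1 log2 unit of 0 on both sides.

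The tested genes of Wnt signalling did not differ detectably in their change between the arms. They were 11 of the 24 fixed Wnt/beta-catenin target genes, without AXIN2 and APCDD1, and 24 of the 40 fixed ligands, receptors and coactivators. The list of 11 Wnt/beta-catenin target genes differed by a mean of 0.04 ± 0.43 (SD, n = 15 patients; interval -0.20 to 0.28; exact sign-flip permutation p = 0.698, adjusted p = 0.991). LEF1, a transcription factor that partners beta-catenin and is itself a Wnt target, differed by 0.20 ± 0.21 (SE), the secreted Wnt antagonist DKK1 by 0.27 ± 0.43 and WIF1, another Wnt antagonist, by -0.23 ± 0.50. The 24 Wnt ligands, receptors and coactivators differed by 0.002 ± 0.22 (SD; interval -0.12 to 0.12). No member of either list passed when adjusted over the list alone or over all genes. Without the array that stood apart LEF1 was at 0.07 and WIF1 at -0.50, the mean for the target genes was -0.03 ± 0.33 (SD) and that for the ligands, receptors and coactivators was -0.05 ± 0.08 (exact permutation p = 0.040, adjusted p = 0.377).

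Markers of fat, fibrosis and inflammation also showed no difference in change past the threshold. The 17 adipocyte genes differed by -0.26 ± 1.10 (SD, n = 15; interval -0.87 to 0.35; adjusted p = 0.991), a list that was read with little precision, and by -0.12 without the array that stood apart. ADIPOQ, the gene of adiponectin, was at -0.38 ± 0.52 (SE), PLIN1, a lipid droplet coat protein, at -0.59 ± 0.57, FABP4 at -0.15 ± 0.28 and PPARG, the regulator of adipocyte differentiation, at -0.15 ± 0.35. TNMD, the most negative member, was at -0.96 ± 0.56 and CIDEA, the most positive, at 0.56 ± 0.37. The 29 collagens and matrix genes differed by -0.01 ± 0.22 (SD; interval -0.13 to 0.11), with COL1A1 at -0.06 ± 0.13 (SE), and the 23 TGF-beta responsive genes by -0.003 ± 0.24 (SD; interval -0.14 to 0.13). COMP and THBS1, TGF-beta responsive genes in the fixed skin score biomarker list, were at 0.06 ± 0.33 and 0.07 ± 0.21 (SE), and SIGLEC1 and IFI44, interferon-responsive members of the same list, at -0.17 ± 0.18 and -0.11 ± 0.16. Without the array that stood apart COMP and THBS1 were at -0.20 and -0.06, SIGLEC1 and IFI44 at -0.06 and -0.07, COL1A1 at -0.11, ADIPOQ at -0.23, FABP4 at -0.10 and PPARG at 0.06. The 4 skin score biomarker genes together differed by 0.002 ± 0.38 (SD; interval -0.21 to 0.22). Without the array that stood apart this list was at -0.05 ± 0.35 and the TGF-beta responsive list at -0.04 ± 0.21. The 24 interferon-stimulated genes differed by -0.08 ± 0.33 (interval -0.26 to 0.10) and the 19 macrophage genes by -0.12 ± 0.73 (interval -0.52 to 0.29), with the scavenger receptor CD163 at -0.23 ± 0.21 (SE). Without that array CD163 was at -0.10 and the macrophage mean was 0.04. The adjusted p of each of these lists was 0.991 or 0.995.

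A pair of lipid lists had the smallest p-values for the difference in change, and neither passed. All 11 cholesterol synthesis genes had a more positive change in the C82 arm, by a mean of 0.34 ± 0.44 (SD, n = 15; interval 0.10 to 0.59; higher in 10 of 15; exact sign-flip permutation p = 0.011, adjusted p = 0.335). The widest were ACAT2, HMGCS1 at 0.63 ± 0.24 (SE) and MSMO1 at 0.63 ± 0.21, and 8 of the 11 passed when adjusted over the list alone against 0 over all genes. The 7 sebaceous gland genes differed by 0.78 ± 1.25 (SD; interval 0.08 to 1.47; higher in 9 of 15; exact permutation p = 0.032, adjusted p = 0.490). GAL was at 1.49 ± 0.61 (SE), HSD3B1, a steroidogenic enzyme, at 1.19 ± 0.53 and FADS2, a fatty acid desaturase, at 1.17 ± 0.38, and 6 of the 7 passed when adjusted over the list alone. Both lists were singled out by their p-values in this same contrast. The counts adjusted over a list alone are therefore no separate evidence of a difference. With a preset correlation between genes, camera called both lists (adjusted p = 2.9e-12 and 7.8e-10) and 12 of the 31 in all. With an estimated correlation it called none, with an adjusted p = 0.095 for both. In the C82 arm itself the cholesterol synthesis list changed by 0.08 ± 0.27 (SD, exact permutation p = 0.260) and the sebaceous gland list by 0.31 ± 1.07 (p = 0.311). In the placebo arm they changed by -0.35 and -0.71, a larger mean change in size, but over 17 patients against 15 for the difference. These values therefore do not split the difference into parts. The C82 minus placebo difference at baseline was -0.22 and -0.52 (n = 16), so the forearms may not have started alike.

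**Figure D1:**
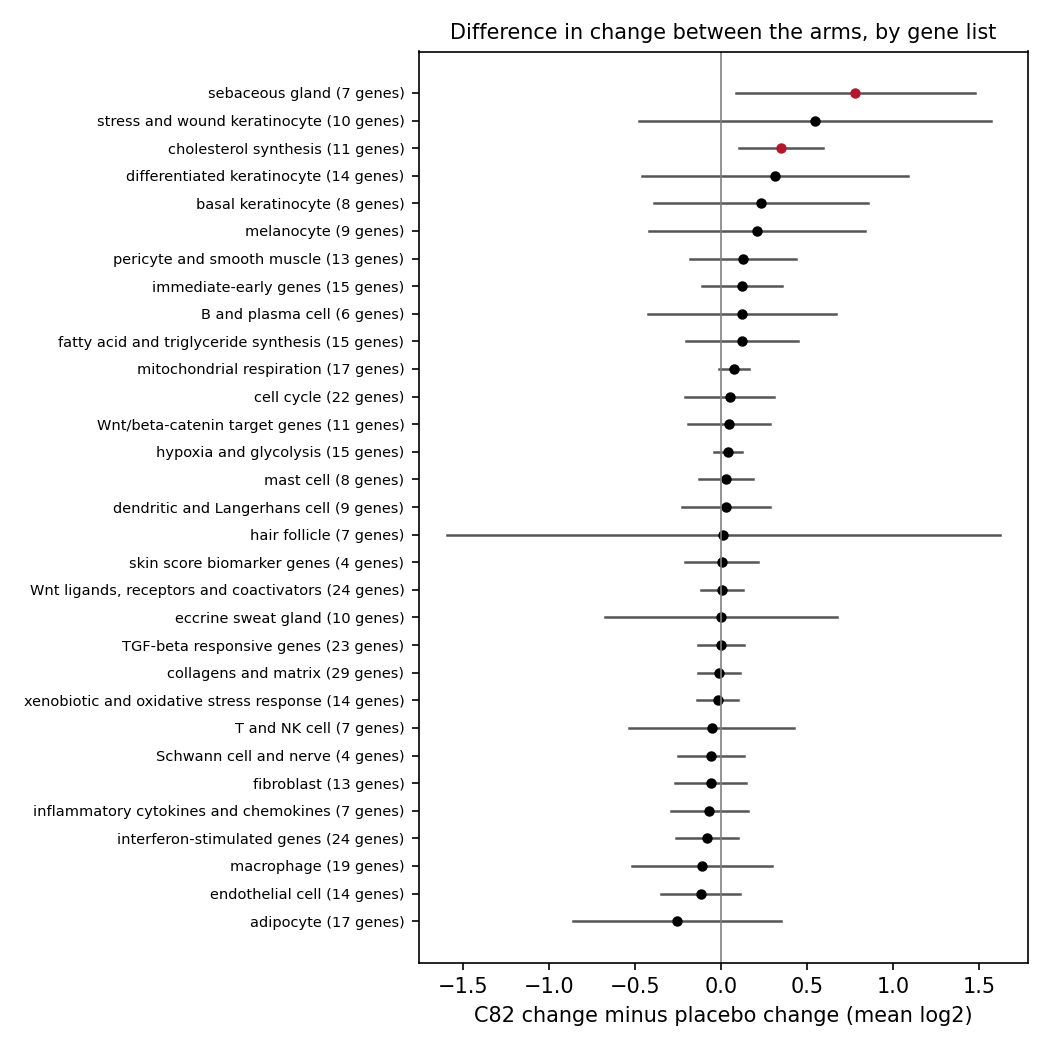
Difference between the change in the C82 arm and the change in the placebo arm for each of the 31 tested gene lists, on the log2 scale. Points are means over 15 patients and lines are 95% intervals. Red points mark the 2 lists with an unadjusted exact permutation p under 0.05, sebaceous gland at 0.78 and cholesterol synthesis at 0.34, neither of which passed after adjustment. The hair follicle, stress and wound keratinocyte and differentiated keratinocyte lists have the widest intervals.

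The remaining lists were examined for the same contrast and lay between -0.12 and 0.54. The endothelial list differed by -0.12 ± 0.42 (SD), the fibroblast list by -0.06 ± 0.37, the pericyte and smooth muscle list by 0.12 ± 0.56, the T and NK cell list by -0.06 ± 0.87 and the B and plasma cell list by 0.12 ± 0.98. The basal, differentiated and stress and wound keratinocyte lists differed by 0.23 ± 1.12, 0.31 ± 1.40 and 0.54 ± 1.85. Hair follicle, eccrine sweat gland and melanocyte lists were at 0.01 ± 2.90, -0.002 ± 1.21 and 0.21 ± 1.13. Dendritic and Langerhans cell, mast cell and Schwann cell lists were at 0.03 ± 0.46, 0.03 ± 0.28 and -0.06 ± 0.35. Among the response lists, the fatty acid and triglyceride synthesis list was at 0.12 ± 0.59, the immediate-early genes at 0.12 ± 0.42, the cell cycle list at 0.05 ± 0.47 and mitochondrial respiration at 0.07 ± 0.15. Inflammatory cytokines and chemokines were at -0.07 ± 0.41, hypoxia and glycolysis at 0.04 ± 0.15 and the xenobiotic and oxidative stress list at -0.02 ± 0.21. No adjusted p was below 0.926. The array that stood apart carried several of these means. Without it the basal, differentiated and stress and wound keratinocyte lists were at -0.05 ± 0.33, -0.04 ± 0.24 and 0.14 ± 1.02, the melanocyte list at -0.05 ± 0.57, the hair follicle list at -0.28 ± 2.78 and the eccrine sweat gland list at -0.23 ± 0.85. The endothelial, pericyte and smooth muscle and fibroblast lists were at -0.05 ± 0.33, 0.04 ± 0.48 and -0.03 ± 0.36. The T and NK cell, B and plasma cell, dendritic and Langerhans cell and Schwann cell lists were at 0.07 ± 0.74, 0.27 ± 0.82, -0.002 ± 0.47 and -0.10 ± 0.31. The fatty acid and triglyceride synthesis list was at 0.23 ± 0.40 (exact permutation p = 0.049, adjusted p = 0.377), the immediate-early genes at 0.06 ± 0.37, the cell cycle list at 0.001 ± 0.45 and inflammatory cytokines and chemokines at -0.03 ± 0.39.

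Within the C82 arm, no gene passed between baseline and day 28 in limma, and 378 had an unadjusted p under 0.05 against 358 by chance. The closest were MT1X, a metallothionein that binds zinc and copper (log2 difference -0.31 ± 0.07 SE, lower in 14 of 15 patients, adjusted p = 0.055), BMP2, a bone morphogenetic protein ligand (-0.47 ± 0.10, lower in 13 of 15, adjusted p = 0.055), and the peptidase gene DPP8 (-0.17 ± 0.04, lower in 13 of 15, adjusted p = 0.055). RABL3 and SNRK followed at -0.27 ± 0.07 and -0.23 ± 0.06. Of the positive differences, those with the smallest p were PANK4 at 0.19 ± 0.05, MEN1 at 0.23 ± 0.06, ATF7IP at 0.24 ± 0.06, EIF4E at 0.22 ± 0.06 and SIRT3 at 0.30 ± 0.08, each with an adjusted p from 0.241 to 0.246. The Wnt/beta-catenin target list had a mean difference of -0.12 ± 0.17 (SD, n = 15; lower in 11; exact sign-flip permutation p = 0.014, adjusted p = 0.431), with WIF1 at -0.57 ± 0.36 (SE), BAMBI at -0.35 ± 0.14 and DKK1 at -0.14 ± 0.31. Its mean in the placebo arm was -0.15 ± 0.44 (SD, n = 17; permutation p = 0.164), and -0.06 ± 0.24 (permutation p = 0.328) without the array that stood apart. The eccrine sweat gland list was at -0.26 ± 0.45 (n = 15; exact permutation p = 0.043, adjusted p = 0.511), with PIP at -1.07 ± 0.60 (SE), SCGB1D2 at -0.63 ± 0.45 and KRT19 at -0.54 ± 0.36. No list passed, and camera with a preset correlation called 13 and with an estimated correlation 0.

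Within the placebo arm, 5 genes changed between baseline and day 28, 2 upward and 3 downward, and 886 had an unadjusted p under 0.05. TMEM260 rose by 0.41 ± 0.09 (SE, higher in 14 of 17 patients) and BANF1, which binds DNA at the nuclear envelope, by 0.28 ± 0.06 (16 of 17). EBP, an isomerase of sterol synthesis, fell by 0.46 ± 0.10 (15 of 17), MT1X fell by 0.30 ± 0.06 (14 of 17) and TFRC, the transferrin receptor, fell by 0.30 ± 0.06 (13 of 17). The adjusted p of all 5 was 0.047, and each lay at 0.106 or more in the least favourable fit with 1 patient left out. No gene passed without the filter on dim genes, with the 60th percentile filter, with quantile normalization, over the patients with all 4 biopsies or without the patient block. Without the array that stood apart 3 passed, 2 of them among the 5. For the difference in change, EBP was at 0.47 ± 0.14, TFRC at 0.27 ± 0.09 and BANF1 at -0.18 ± 0.09, all with an adjusted p of 0.994. Genes just short of the threshold, each with an adjusted p of 0.059, were SNTB2 (0.36 ± 0.08), UBTF (0.29 ± 0.07), TNPO1 (0.24 ± 0.06), FHOD1 (0.37 ± 0.09) and ZBTB38 (0.42 ± 0.10) on the positive side. On the negative side were MT1HL1 (-0.60 ± 0.14), PLIN3 (-0.29 ± 0.07), ATP6V0B (-0.19 ± 0.04), PDZD8 (-0.22 ± 0.05) and ACAT2 (-0.52 ± 0.13).

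In the placebo arm 5 lists had an unadjusted p under 0.05, and none passed; camera called 11 with a preset and 0 with an estimated correlation. Cholesterol synthesis differed by -0.35 ± 0.45 (SD, n = 17; lower in 12; exact permutation p = 0.004, adjusted p = 0.137; adjusted p = 0.336 in camera with an estimated correlation), with HMGCS1 at -0.52 ± 0.16 (SE) and MSMO1 at -0.48 ± 0.15. The sebaceous gland list was at -0.71 ± 1.05 (lower in 12 of 17; adjusted p = 0.152), with GAL at -0.90 ± 0.42, HSD3B1 at -0.90 ± 0.37 and FA2H at -0.84 ± 0.31. Immediate-early genes were at -0.23 ± 0.37 (lower in 14 of 17; adjusted p = 0.157), with FOS at -0.70 ± 0.32, CCN1 at -0.44 ± 0.17 and EGR3 at -0.39 ± 0.17, or -0.22 without the array that stood apart. The immediate-early list itself was at -0.17 ± 0.28 without that array (exact permutation, adjusted p = 0.313). All 24 interferon-stimulated genes were positive, with a mean of 0.21 ± 0.39 (higher in 11 of 17; adjusted p = 0.283) and CXCL10 at 0.73 ± 0.25, XAF1 at 0.36 ± 0.11 and RSAD2 at 0.35 ± 0.14. This list was at 0.18 ± 0.37 without the array that stood apart, no longer under 0.05 (exact permutation p = 0.071, adjusted p = 0.424). The basal keratinocyte list was at -0.33 ± 0.91 (lower in 12 of 17; adjusted p = 0.293), with CDH3 at -0.67 ± 0.35, DST at -0.54 ± 0.25 and KRT5 at -0.46 ± 0.23. Without the array that stood apart the list was at -0.11 ± 0.26 (exact permutation p = 0.095, no longer under 0.05), CDH3 at -0.19, DST at -0.22 and KRT5 at -0.14.

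Taking both arms together, 54 genes passed between baseline and day 28, 32 upward and 22 downward, and all changes were small, the largest 1.35-fold. The fit took the changes of a patient's forearms as independent. Across genes these correlated with a median of 0.196 within a patient and 0.032 between patients. The standard errors and adjusted p-values over both arms may therefore be too small, and the count of 54 too high. Metallothionein genes, whose products bind zinc and copper, made up 7 of the 22 that fell. MT1X fell by 0.31 ± 0.05 (SE, lower in 14 of 15 patients, limma adjusted p = 1.3e-04), MT2A by 0.27 ± 0.05 (13 of 15), MT1F by 0.33 ± 0.06 (15 of 15), MT1E by 0.26 ± 0.05, MT1G by 0.28 ± 0.06, MT1H by 0.35 ± 0.07 and MT1HL1 by 0.44 ± 0.10 (12 of 15 for each of these). Their probe sets are of the Affymetrix type that matches related transcripts, so the family members cannot be read as independent. The mean of the 8 tested members was -0.31 after quantile normalization as well. BMP2 fell by 0.42 ± 0.07 (14 of 15, adjusted p = 8.5e-04), and was at -0.47 ± 0.10 in the C82 arm and -0.37 ± 0.10 in the placebo arm, in neither of which it passed alone. FJX1 fell by 0.26 ± 0.06, EPB41L4B by 0.23 ± 0.06, TFDP2, a partner of E2F transcription factors, by 0.19 ± 0.05 (passing in 5 of 17 fits with a patient left out), and PDZD8 by 0.18 ± 0.04.

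Among the genes that rose over both arms, ZBTB38, a zinc finger protein that binds methylated DNA, rose by 0.34 ± 0.07 (14 of 15), DICER1, the ribonuclease that matures microRNAs, by 0.30 ± 0.07 (13 of 15), CMTR1, an mRNA cap methyltransferase, by 0.28 ± 0.06 (13 of 15), KMT2A, a histone methyltransferase, by 0.26 ± 0.06 (12 of 15) and CREB1, the cAMP response element binding protein, by 0.24 ± 0.05 (13 of 15). XAF1 and OAS1, members of the interferon-stimulated list, rose by 0.31 ± 0.08 and 0.24 ± 0.06 (12 of 15 each). The others with the largest increases were FNDC3B (0.33 ± 0.08), FHOD1, a formin (0.27 ± 0.06), TMEM260 (0.27 ± 0.06), the mannosidase gene MAN2C1 (0.24 ± 0.06) and SNTB2, a syntrophin (0.24 ± 0.06). With each patient left out in turn, KMT2A and SNTB2 passed in 9 of 17 fits, XAF1 in 8 and OAS1 and MAN2C1 in 7. All 54 had the same sign in each arm, and 2 had an unadjusted p under 0.05 for the difference in change. In limma without the patient block no gene passed, and without the array that stood apart 82 passed, 51 of them among the 54.

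**Figure D2:**
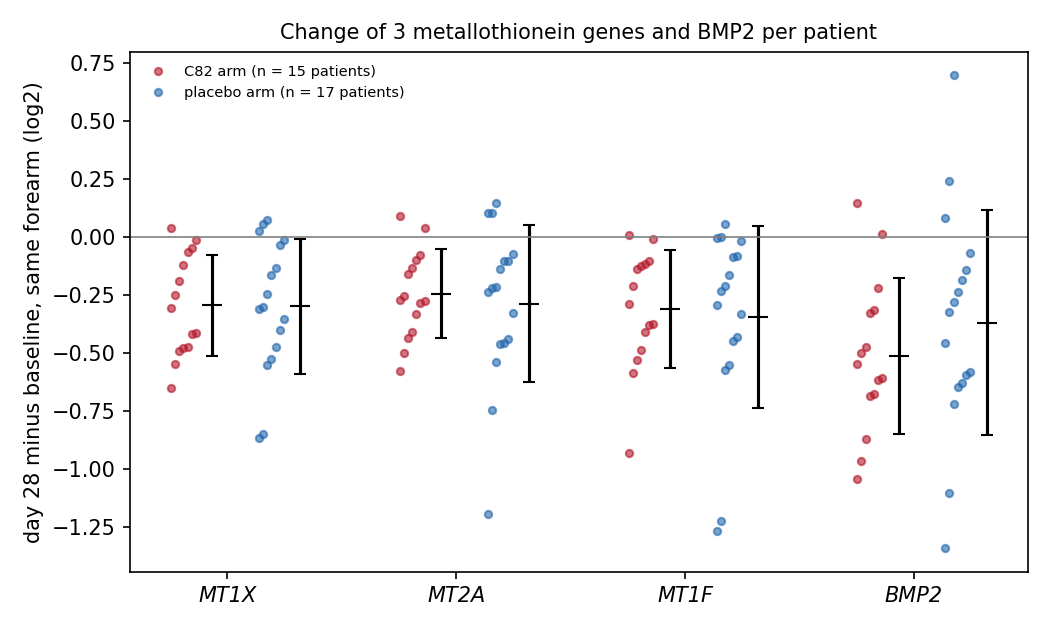
Day 28 minus baseline on the same forearm, on the log2 scale, for the metallothionein genes MT1X, MT2A and MT1F and for BMP2. Each point is 1 patient (15 in the C82 arm, 17 in the placebo arm) and the black marks give the mean and SD. Most points lie below 0 in both arms, and for MT1X 14 of 15 in the C82 arm and 14 of 17 in the placebo arm do.

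Of the lists, basal keratinocyte markers fell over both arms by 0.21 ± 0.42 (SD, n = 15; interval -0.44 to 0.03; lower in 13 of 15; exact sign-flip permutation p = 0.001, adjusted p = 0.038). The call was lost in camera (adjusted p = 0.630 with an estimated correlation) and without the array that stood apart, where the mean was -0.10 ± 0.12 with an adjusted p of 0.076. All 8 members were negative, with CDH3 at -0.36 ± 0.26 (SE), DST at -0.35 ± 0.18 and KRT15 at -0.32 ± 0.20, and none passed over all genes or adjusted over the list alone. Without that array these 3 were at -0.12, -0.19 and -0.15. Of the other lists, 2 had an unadjusted p under 0.05. The Wnt/beta-catenin target list was at -0.15 ± 0.28 (lower in 11 of 15; adjusted p = 0.215), with WIF1 at -0.45 ± 0.25, BAMBI at -0.29 ± 0.09 and DKK1 at -0.27 ± 0.21 over all arrays. Without the array that stood apart the mean of this list was -0.08 ± 0.12. Immediate-early genes were at -0.18 ± 0.29 (lower in 12 of 15; adjusted p = 0.248), with FOS at -0.64 ± 0.23, DUSP1 at -0.26 ± 0.11 and CCN1 at -0.26 ± 0.12. Interferon-stimulated genes were at 0.11 ± 0.29 (adjusted p = 0.450), where 6 of 24 passed when adjusted over the list alone against 2 over all genes, and XAF1, OAS1 and CXCL10 were at 0.31, 0.24 and 0.48. The mean of this interferon list was 0.08 ± 0.26 without the array that stood apart.

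At day 28 itself, no gene separated C82-treated from placebo-treated skin in limma, and 216 had an unadjusted p under 0.05 with a smallest adjusted p of 0.975. The smallest p-values belonged to TFB2M (0.21 ± 0.06 SE), MSH3 (0.32 ± 0.09), SIPA1L3 (0.29 ± 0.09), the zinc exporter gene SLC30A1 (0.20 ± 0.06) and FASTKD1 (0.16 ± 0.05) on the positive side. On the negative side they belonged to CSF1, the macrophage growth factor (-0.32 ± 0.09, lower in 12 of 16 patients), BACE1 (-0.17 ± 0.05), APOL2 (-0.24 ± 0.08), MXRA8 (-0.25 ± 0.08) and PHF20 (-0.11 ± 0.04). Interferon-stimulated genes were the only list with an unadjusted p under 0.05, at -0.11 ± 0.20 (SD, n = 16; lower in 14 of 16; exact sign-flip permutation p = 0.044, adjusted p = 0.981), with OAS2 at -0.26 ± 0.11 (SE), RSAD2 at -0.24 ± 0.14 and IFI6 at -0.23 ± 0.10. The Wnt/beta-catenin target list was at 0.04 ± 0.37 (SD), with LEF1 at 0.27 ± 0.15 (SE), and the adipocyte list at -0.27 ± 1.15 (SD). Without the array that stood apart these lists were at -0.04 ± 0.17 and -0.10 ± 0.95 and LEF1 at 0.14. The interferon-stimulated list was then at -0.10 ± 0.20 (exact sign-flip permutation p = 0.078), no longer under 0.05.

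At baseline, before treatment, no gene differed between the forearms later given C82 and placebo in limma, and 228 had an unadjusted p under 0.05. The negative differences with the smallest p-values, none of which passed, were PLIN2, a lipid droplet protein, at -0.48 ± 0.13 (SE, lower in 13 of 16 patients), SOAT1 at -0.71 ± 0.21 (14 of 16), PLA2G7 at -0.56 ± 0.17, BCAT2 at -0.46 ± 0.13 and TMEM164 at -0.31 ± 0.10. On the positive side were PCBP4 at 0.35 ± 0.10, SCMH1 at 0.21 ± 0.07, LTA4H at 0.14 ± 0.05, PTP4A3 at 0.32 ± 0.11 and FADD at 0.12 ± 0.04. Cholesterol synthesis genes were lower on the C82 forearm by a mean of -0.22 ± 0.38 (SD, n = 16; lower in 11; exact permutation p = 0.032, adjusted p = 0.636), and the sebaceous gland list was at -0.52 ± 0.98 (lower in 12; exact permutation p = 0.054, adjusted p = 0.636).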

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

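The test of the cholesterol list against the sebaceous gland list was set before its result was seen, and the others in this part were chosen after the values had been seen. The 2 gene lists here were singled out because their change differed between the arms at an unadjusted p under 0.05. These were cholesterol synthesis, with a difference of 0.34 (log2, n = 15 patients), and sebaceous gland, with 0.78. Neither passed after adjustment over 31 lists, among which chance gives 1.55 at that level.

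For cholesterol synthesis the arms differed by -0.22 at baseline (interval -0.42 to -0.02) and by 0.15 at day 28 (interval -0.06 to 0.35), but the baseline value is part of the difference for which the list was singled out and had an adjusted p of 0.636, so a difference between the forearms before treatment stays open. Over the 15 patients the cholesterol difference followed that of the sebaceous gland list (Pearson r = 0.609, permutation p = 0.019, Spearman rho = 0.614, permutation p = 0.018). Without the 2 patients farthest from the median r was of like size at 0.555 with a permutation p of 0.051. At no difference in the sebaceous list the cholesterol difference was 0.18 (interval -0.06 to 0.42), against 0.34 before. The correlation and this fall may reflect how much sebaceous gland single biopsies caught. An effect of C82 on lipid genes was neither shown nor excluded, since the interval at no sebaceous difference, -0.06 to 0.42, includes no difference. Chance stays open too, as the list did not pass after adjustment. The cholesterol list changed by only 0.08 ± 0.27 (SD, n = 15) in the C82 arm itself, against -0.35 (n = 17) in the placebo arm.

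One array of the placebo arm at day 28 differed from all others in its tissue markers and had a median log2 value over genes of 7.67 against 7.70 or more in the others. Its adipocyte list lay above, and both its basal and differentiated keratinocyte lists below, the range of all other arrays, with the adipocyte list at 2.87 log2 units above the same patient's other biopsies. This is consistent with a biopsy rich in subcutaneous fat and poor in epidermis. Its 3' to 5' log2 ratio of 0.29 lay inside the range of -0.16 to 0.47 of the other arrays, above the placebo day 28 mean of 0.05 ± 0.15 (SD), which leaves RNA degradation open. A sample from elsewhere under this label was not tested, and no biological explanation was tested.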

How the results depend on the processing

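The alternatives chosen after seeing the data were the fit without the array that stood apart and the fit with keratinocyte and adipocyte list means as covariates. The counts of 0 genes for the difference in change, for day 28 and for baseline were 0 under every alternative run, at an adjusted p under 0.1 as well. In the C82 arm the main count of 0 became 2 with a 60th percentile filter, 1 with array weights, 3 at an adjusted p under 0.1, and 0 to 2 when each patient was left out. In the placebo arm the 5 genes became 0 without a filter on dim genes, with the 60th percentile filter, with quantile normalization, without the replicate block and over patients with all 4 biopsies. They became 22 with the mean of a gene's probe sets and with array weights, 13 with every probe set tested, 63 at an adjusted p under 0.1, 3 without the array that stood apart, 16 with the covariates, and 0 to 29 over the patients left out, where 14 of 17 fits moved the count by over 1.5 times. The 54 genes changed from baseline to day 28 over both arms became 31 without the filter, 28 with the 60th percentile filter, 0 without the block, 114 with every probe set tested, 107 at an adjusted p under 0.1, 82 without the array that stood apart, 143 with the covariates, and 21 to 74 over the patients left out. The loss without the block follows from leaving the differences between patients in the residual, and more tests were made with every probe set. The cause of the other moves was not tested. MT1X, MT2A, MT1F, MT1H, MT1E, BMP2, PDZD8, CMTR1 and ZBTB38 passed in all 17 fits with a patient left out. TFDP2 passed in 5, OAS1 and MAN2C1 in 7, XAF1 in 8, KMT2A and SNTB2 in 9, FJX1 in 11, EPB41L4B in 12, FNDC3B, DICER1, TMEM260 and MT1G in 14, FHOD1 in 15 and CREB1 and MT1HL1 in 16.

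For the lists, the 1 called over both arms became 0 without the filter, with the mean of probe sets, without the array that stood apart and with camera's estimated correlation, and 0 to 2 over the patients left out. The C82 and placebo arms each had 0 to 1 over the patients left out. Camera with a preset correlation called, with and without the replicate block, 13 and 6 lists in the C82 arm, 11 and 10 in the placebo arm, 12 and 15 for the difference in change, 13 and 13 at day 28, 3 and 3 at baseline and 12 and 6 over both arms.

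Among the genes named by the rule and the lists followed through each alternative, which leave out part of the 31 lists, signs turned for differences in change, or at day 28, that had not passed. PPARG turned to 0.085 with array weights, 0.064 without the array that stood apart, 0.15 with the covariates and -0.30 to 0.022 over the patients left out. COMP turned to -0.026, -0.20, -0.17 and -0.22 to 0.18 in the same order, and THBS1 to -0.020, -0.063, -0.047 and -0.033 to 0.14. FABP4 turned to 0.00611 with the covariates and -0.23 to 0.017 over the patients left out. The TGF-beta responsive genes list turned to 0.044 with the 60th percentile filter, 0.047 with the mean of probe sets and -0.037 to 0.032 over the patients left out. The skin score biomarker genes list turned to -0.000694 with quantile normalization, -0.045 without the array that stood apart and -0.056 to 0.049 over the patients left out. Without that array the Wnt/beta-catenin target genes list turned to -0.031 for the difference in change and -0.041 at day 28, and the macrophage list to 0.035. Over the patients left out these were -0.031 to 0.081, -0.041 to 0.066 and -0.18 to 0.035, and the collagens and matrix list was at -0.040 to 0.014. Of all 31 lists, without the array that stood apart 5 turned in the placebo arm, 10 for the difference in change, 12 at day 28 and 3 over both arms, and 0 in the C82 arm and at baseline. Of 1431 alternative values of those genes and followed lists, 1281 kept their direction and side of the threshold, 98 were no longer past it, 25 came past it and 27 turned. MAS5 signals near background limit the dim genes, and the genes under the 40th percentile were left out.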

Other observations

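The relations between lists, the metallothionein tests and the count of splits in this part were chosen after the main results had been seen. The correlation between the changes of the arms was set before its result was seen, but how it was read was altered afterwards, as given beside it. Across the 17 patients at baseline, with the mean of a patient's baseline biopsies, fibrotic and immune marker lists varied together in part. Of 28 relations among 8 lists, 4 passed adjustment by Pearson's r and 6 by Spearman's rho. Collagens and matrix genes were higher with higher TGF-beta responsive genes (Pearson r = 0.827, permutation p = 6e-05, adjusted p = 0.002, Spearman rho = 0.809, permutation p = 1.7e-04, r = 0.673 without the 2 patients farthest from the median). T and NK cell markers were higher with higher B and plasma cell markers (r = 0.760, permutation p = 2.9e-04, adjusted p = 0.004, rho = 0.789, permutation p = 2.7e-04, r = 0.693 without 2). TGF-beta responsive genes were higher with higher macrophage markers (r = 0.632, permutation p = 0.006, adjusted p = 0.048, rho = 0.740, permutation p = 8.3e-04, r = 0.618 without 2). Wnt/beta-catenin target genes were lower where macrophage markers were higher (r = -0.631, permutation p = 0.007, adjusted p = 0.048, rho = -0.645, permutation p = 0.006, r = -0.649 without 2). Past adjustment by rho alone were T and NK cell markers with macrophage markers (rho = 0.733, permutation p = 0.00147, adjusted p = 0.010, r = 0.582, permutation p = 0.015, adjusted p = 0.071, r = 0.456 without 2) and with Wnt/beta-catenin target genes (rho = -0.635, permutation p = 0.00757, adjusted p = 0.035, r = -0.457, permutation p = 0.066, adjusted p = 0.143, r = -0.423 without 2). Interferon-stimulated genes had no such relation with collagens (r = 0.168, permutation p = 0.522, rho = 0.225, permutation p = 0.383, r = 0.127 without 2, adjusted p = 0.562). No relation of the adipocyte list passed by r or rho. Its r ran from -0.48 to -0.33 with the matrix, TGF-beta, interferon and immune cell lists and was 0.49 with the Wnt/beta-catenin target genes. Whether the relations among the 8 lists arose from the tissue make-up of the biopsies was not tested. The labels give no batch within which these relations could be repeated.

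The metallothionein family was picked because its members stood among the 54 called genes, so no test of whether it was lower is given. Of 8 tested members, 7 were called over both arms, with members that share probe sequence and so are not independent. The exception, MT1M, was at -0.37 with an adjusted p of 0.145, and is the 1 member whose probe set is not of the type that matches related transcripts. The family mean was -0.28 ± 0.27 (SD, lower in 12 of 15 patients) in the C82 arm and -0.36 ± 0.40 (lower in 14 of 17) in the placebo arm, and the difference in change was 0.07 (interval -0.10 to 0.23; exact sign-flip permutation p = 0.479). In the fitted model the change over both arms was -0.33 (interval -0.45 to -0.20). It was -0.33 (interval -0.45 to -0.21) with the 3' to 5' ratio as a covariate, on which 83 genes depended. The ratio itself hardly differed between the days over both arms (0.02 ± 0.15, SD over 15 patients, exact sign-flip permutation p = 0.716). This covariate could therefore hardly move the change, and the fit does not test degradation that the ratio misses. The change was -0.31 (interval -0.43 to -0.18) with keratinocyte and adipocyte list means as covariates, on which 3153 genes depended. The family had been picked as lower, so an interval below 0 was likely in any such fit. These fits also took the changes of a patient's forearms as independent, so their intervals may be too narrow. The estimate hardly moved. The residual SD of the basal keratinocyte list was 0.51 with the array that stood apart and 0.17 without it, so that array weighed heavily on this covariate. The family fit was not repeated without the array, so it does not decide whether a lower share of epidermis was the cause. Over the patients the family's change correlated with that of the basal keratinocyte list (r = 0.454, not tested), so a contribution of epidermis stays open. A candidate explanation that stays open is something both forearms shared, such as the time since the baseline biopsy or the vehicle, and no untreated skin was there to test it. Baseline and day 28 arrays run at different times would shift both arms alike too, and the labels give no date or batch to test that.

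Swapping labels within random patients tested whether chance could give the counts. For the change over both arms 2 of 100 splits, the real one included, gave at least 54 genes, and the highest other gave 430. What made that split call so many genes was not tested. For the placebo arm 1 of 100 gave at least 5 genes and the highest other gave 1. Of the other splits, 18 over both arms and 6 in the placebo arm called at least 1 gene. Both shares lie under 0.05, but 1 of 100 is the smallest share this number of splits can give. Counts this large were uncommon among the splits, which does not exclude chance. The split with 430 genes also leaves the count of 54 weak as evidence. The 5 genes of the placebo arm became 0 in 6 of 17 fits with a patient left out and under 5 other alternatives, which leaves that count weak too. Any split meets a count of 0, so the 100 of 100 splits for the C82 arm, the difference in change, day 28 and baseline say nothing about chance, and their highest others were 1, 0, 1 and 1.

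A change over time shared by the patients was tested as a hypothesis from the mean changes of the 2 arms, which correlated across 7163 genes (r = 0.374, genes not being independent). When the sign of both arms' changes was flipped in random patients, 2000 draws gave a median of 0.108 and a 95th percentile of 0.392, so the value lay within 95% of the draws (p = 0.065). By the criterion set beforehand that counts against the hypothesis. The criterion was judged wrong after the value had been seen, because a value above the median of the draws and under their 95th percentile fails to show a shared change and does not rule one out, and the hypothesis is therefore left open. Within a patient the changes of the 2 forearms correlated with a median of 0.196, above 0 in 11 of 15 patients, and between different patients with 0.032.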
